A study of Homo sapiens with 18 samples.

How the data were processed

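Total RNA of a human T cell line was measured on 18 Affymetrix arrays in 6 groups of 3. The series title names the CEM line, while the sample labels name blood as the source. The deposited table holds intensity values on a linear scale with no detection calls. The software that made the values is not given in the sources used here. The mean of each array after trimming 2% at each end was 150.0 after rounding, so the arrays had been scaled as a whole to one target. Between 33.3% and 43.5% of the values of an array lay below an intensity of 16.

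The following choices were made before the data were examined, unless stated otherwise: the groups, comparisons, tests, gene lists and the rule for named genes. Values were taken as log2(intensity + 16). Array medians of these values ranged over 0.371 log2 units, beyond the tolerance of 0.2 that had been set, so arrays were quantile normalized in the main analysis and the values as deposited served as an alternative. Array control probe sets, 62 in number, were left out, and probe sets with a mean at or above the 40th percentile of all were kept, 32768 in number for 13352 genes. The offset compresses fold changes of dim genes. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed in the annotation table. Chromosome positions were not used here.

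Differences were tested with limma 3.58.1 in R 4.3.3: 1 mean per group over all 18 arrays, moderated variances with a trend on mean level, two-sided tests and Benjamini-Hochberg adjustment over the probe sets kept, with calls at an adjusted p under 0.05. The comparisons were each nicotine group against its untreated group, 1 mM against 10 nM and 10 µM at 1 h, any dose at 1 h by an F test, the 10 µM effect at 24 h minus that at 1 h, and the untreated groups against each other. The untimed controls served for the 1 h doses, since no label gives their time. Tables were prepared with Python 3.11.15 and numpy 2.4.6, and figures with matplotlib 3.10.9.

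Of 27 gene lists fixed beforehand, covering signalling, stress, metabolism, the cell cycle and markers of other blood cells, 26 had the required 5 kept genes. The list of other cholinergic genes had fewer and was not tested. Each gene was represented by its probe set of highest mean. Lists were tested with camera at an inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison, with the estimated correlation and fry beside it. Camera compares a list with all other genes, whereas fry asks whether its genes move one way on balance.

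The genes named were, for each nicotine group, up to 12 called genes raised and 12 lowered with the largest change and all 3 treated arrays beyond all 3 controls. Where fewer than 10 genes were called, the 10 probe sets of smallest unadjusted p were added, marked as not passing. For the other comparisons up to 6 raised and 6 lowered called genes were taken. Called list members, up to 4 members of smallest p per list described, and a fixed set of 12 genes were also taken. Of that set CHRNA7, FOS, HMOX1, HSPA1A and CYP1A1 had no kept probe set with a single symbol. Genes called with the block of 3 sets but not in the main fit, and EGLN3, are named in addition, chosen after their values were seen. A gene was shown by its called probe set of largest change, otherwise by its probe set of highest mean, or for the smallest p by the probe set that had it.

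The labels number the untreated arrays and most treated arrays from 1 to 3, while the first nicotine array of each 1 h dose has no number. Whether numbers pair arrays was checked on residuals from the group means: at 1 h the 18 pairs of equal number correlated at 0.19 to 0.57 and the 36 other pairs at -0.41 to 0.03, while the 3 pairs at 24 h lay between -0.03 and 0.00. The block fixed beforehand used numbers 2 and 3 at 1 h and 1 to 3 at 24 h. A block of 3 sets, in which the unnumbered array counts as number 1 because its group also holds 2 and 3, was added after the data were seen.

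Alternatives fixed beforehand were offsets of 1 and 64, the values as deposited, median centring, no filter, a filter at the 60th percentile, variances without a trend, only the arrays compared, array weights, 1 probe set per gene, the planned block and leaving out each array in turn. For lists they were the estimated correlation, fry, the median over a gene's probe sets, the offsets, normalization, filter, block and leaving out arrays. Added later were the block of 3 sets, that block with an estimated correlation, and median centring and the arrays compared alone for lists. When an array was left out, the normalization from all 18 was kept. Correlations between doses were set against unchanged groups simulated on the same controls, 50 times. The fit was tested on simulated data with 50 probe sets changed at each of 4 folds.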

Results

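RNA of CEM, an established human T cell line grown from an acute lymphoblastic leukaemia, was measured on 18 oligonucleotide expression arrays. Nicotine is an agonist of nicotinic acetylcholine receptors. The labels give 6 groups of 3 arrays: untreated cells, cells given 10 nM, 10 µM or 1 mM nicotine for 1 h, untreated cells at 24 h, and cells given 10 µM nicotine for 24 h. The untreated arrays compared with the 1 h doses carry no time in their labels and are called the untimed controls here. The number of arrays limits the precision: the 95% confidence interval of a difference between 2 groups had a median half-width of 0.545 log2 units. It was 0.423 with the block of 3 sets. The error of the main fit is shared over all 18 arrays and includes the differences between the replicate sets at 1 h. The labels do not say whether replicates are separate cultures, so the p-values may not measure the spread between cultures. The spread among the 24 h arrays may be technical only. Levels are given as log2 intensity, mean ± SD of 3 arrays, and differences as log2 values ± SE between groups of 3 arrays.

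After 24 h in 10 µM nicotine, genes of the hypoxia and glycolysis list, which holds glycolytic enzymes and targets of hypoxia-inducible factor, were lower as a group than in the 24 h controls. The list fell by a median of 0.55 log2 units, and 25 of its 26 measured genes had a lower mean, all but EGLN3. PFKFB4, an enzyme that sets the level of the glycolytic regulator fructose 2,6-bisphosphate, stood at 4.65 ± 0.55 with nicotine against 7.30 ± 0.49 without, a difference of -2.65 ± 0.52. ADM, the secreted peptide adrenomedullin, differed by -2.17 ± 0.36, and BNIP3, a mitochondrial protein that acts in mitophagy, by -1.92 ± 0.68. BNIP3 also varied between the replicate sets of the 1 h arrays, by -1.95 for number 2 against 1. Its mean level was 8.47 in the untimed controls, 10.13 in the 24 h controls and 8.20 with nicotine at 24 h. Abundant glycolytic enzymes differed by less: lactate dehydrogenase LDHA by -0.56 ± 0.29 and enolase ENO1 by -0.69 ± 0.34. PFKFB4 and ADM were near background with nicotine, so their differences depend on the offset and ranged from -4.11 to -1.48 and from -2.52 to -1.10 over the alternatives. The list test gave an adjusted p of 2.6e-23 with camera, 0.011 with an estimated correlation and 0.0286 with fry. Over all genes tested with limma, 0 members passed, while 7 were lower adjusted over the list alone. With a block for the replicate numbers of the 1 h arrays, a setting chosen after the data were seen, 11 members were lower over all genes and 24 adjusted over the list alone. These counts leave the spread between the 1 h sets out of the error and may rest on technical spread only. Leaving out each of the 6 arrays in turn kept the list's median between -0.64 and -0.48. The ratio of 3' to 5' signal of ACTB, a sign of RNA quality, was 2.69 to 3.27 in the 24 h controls and 2.81 to 3.01 with nicotine. Scores of B cell markers were -0.26 to -0.20 with nicotine against -0.02 to 0.21 in the 24 h controls, and those of myeloid markers -0.30 to 0.05 against 0.09 to 0.27. Neither of these lists was called, with adjusted p of 0.464 and 0.537.

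**Figure D1:**
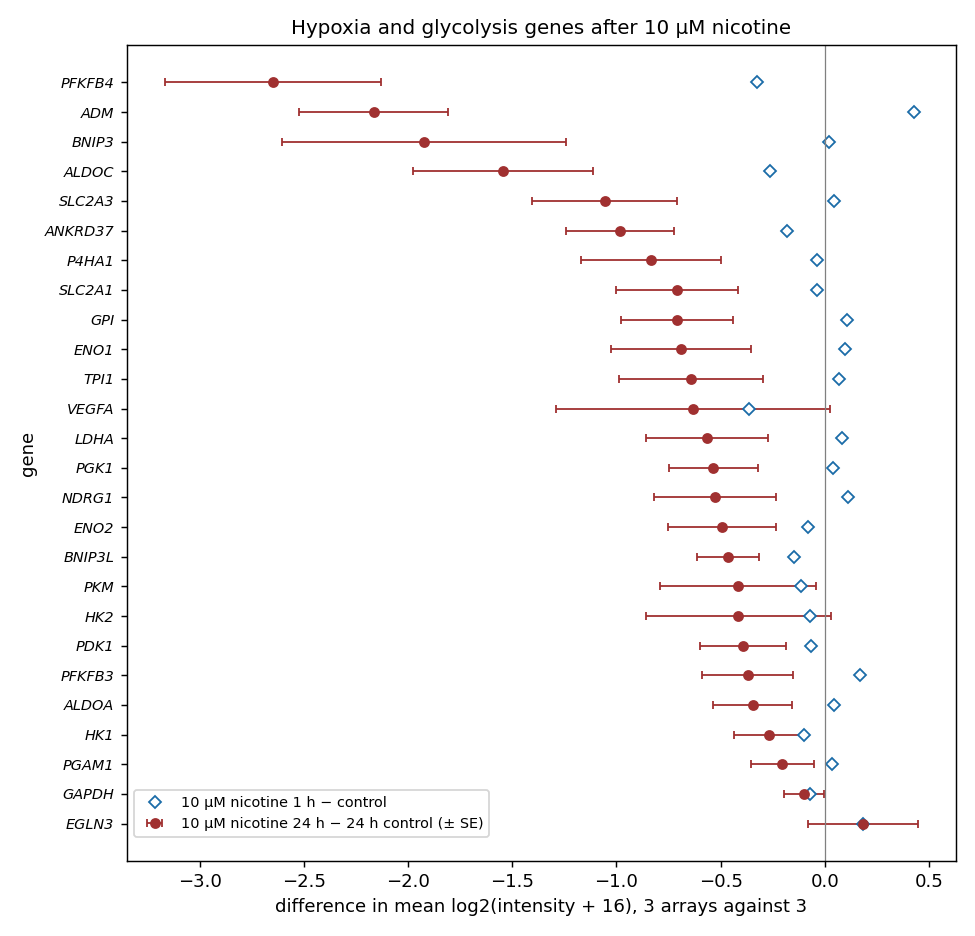
Log2 difference in expression between nicotine and control for each of the 26 measured genes of the hypoxia and glycolysis list; circles with bars are 10 µM nicotine at 24 h (difference ± SE, 3 arrays against 3) and diamonds are 10 µM at 1 h. At 24 h 25 of the 26 genes lie below 0, down to -2.65 for PFKFB4, whereas at 1 h 13 lie below 0 and 13 above.

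Genes of cholesterol and fatty acid synthesis also had lower means at 24 h with nicotine: the median of the list fell by 0.24 log2 units, with 18 of 23 genes lower. The scores of single arrays overlapped, at -0.94 to -0.77 with nicotine against -0.80 to -0.55 in the 24 h controls. The camera test gave an adjusted p of 1.2e-06, but an adjusted p of 0.366 with an estimated correlation and 0.637 with fry. The desaturase SCD differed by -0.49 ± 0.13, the sterol reductase DHCR7 by -0.59 ± 0.21 and the mevalonate kinase MVK by -0.37 ± 0.14. Over all genes 0 members passed, and 1 was lower adjusted over the list alone. Immediate early genes, which growth signals switch on within minutes, were not called: the list's median difference was -0.14 with an adjusted p of 0.0529. This list passed in 7 of 12 alternatives, with an adjusted p of 0.00822 with the block of 3 sets, but an adjusted p of 0.120 with that block and an estimated correlation. The probe set of EGR1 with the largest signal differed by -2.71 ± 0.58 with an adjusted p of 0.602. The other EGR1 probe sets differed by -1.55 and 0.08. Of the 26 lists tested, the remaining 23 were not called, with adjusted p from 0.316 to 0.957. Of the nicotinic receptor subunits, CHRNA5 differed by 0.09 ± 0.16, and the activation genes CD69 and IL2RA by -0.31 ± 0.29 and -0.16 ± 0.38. MYC differed by 0.20 ± 0.22 and the NF-kB inhibitor NFKBIA by -0.19 ± 0.22, and none of these 5 genes passed.

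A single probe set passed on its own at 24 h with nicotine. It measures RHOT2, a GTPase of the outer mitochondrial membrane that links mitochondria to transport motors, and rose by 1.58 ± 0.21, with an adjusted p of 0.0149. Its intensity in the 24 h controls was near background, so the size depends on the offset: 2.59 with an offset of 1 and 0.76 with an offset of 64. It was higher in all 3 treated arrays than in any control array. Its level was 6.27 ± 0.20 with nicotine and 4.69 ± 0.31 in the 24 h controls, against 6.76 ± 0.11 in the untimed controls. The other RHOT2 probe sets differed by 1.08 and -0.09. The last of these was the brightest, at 7.08 in the 24 h controls and 6.99 with nicotine. The count at an unadjusted p under 0.05 was 1186 of 32768 probe sets. Of the other 9 probe sets with the smallest p, IGFBP2, a carrier of insulin-like growth factors, differed by -1.40 ± 0.23 with an adjusted p of 0.103, and ADM, PFKFB4, EGR1, PROSER2 and RIPOR3-AS1 were likewise lower without passing. ATAD2B, TRPM7 and THRAP3 were higher by 0.83, 1.10 and 1.21 without passing, and their other probe sets did not all share that direction. The 24 h controls also enter the comparison of the untreated groups given below, with opposite sign. There RHOT2, TRPM7 and THRAP3 differed by -2.07, -1.88 and -1.74. ADM, EGR1 and BNIP3 differed there by 2.15, 2.08 and 1.66. A deviation of the 24 h control arrays would appear in both comparisons. IGFBP2 had no such mirrored difference, at 9.43 in both untreated groups. The RHOT2 call was lost with an offset of 64, with the values as deposited, without the filter, in a fit of the 24 h arrays alone, and without any of the 6 arrays but replicate 1 of the 24 h controls, with adjusted p from 0.0642 to 0.25 when an array was left out.

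With the block of 3 replicate sets, 43 probe sets in 33 genes passed at 24 h, 4 higher and 39 lower. Of these genes 13 belong to the hypoxia and glycolysis list by at least 1 probe set and 2 to the cholesterol and fatty acid list. Besides those named above they included the triose phosphate isomerase TPI1, which fell by 0.64, the collagen prolyl hydroxylase P4HA1, which fell by 0.83, and the glucose transporter SLC2A3, which fell by 1.06. The sterol enzyme HMGCS1 fell by 0.73. The block acts on the spread of the 1 h arrays only, since the 24 h numbers did not pair their arrays, with correlations between -0.03 and 0.00 for the 3 pairs of equal number. It takes the spread between the 1 h sets out of the error, and the SE of BNIP3 fell from 0.68 to 0.21. The labels do not say whether the 24 h arrays are separate cultures, so these calls may rest on technical spread only. A fit of the 24 h arrays alone called 19 probe sets, all lower, of which 18 were among the 43.

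**Figure D2:**
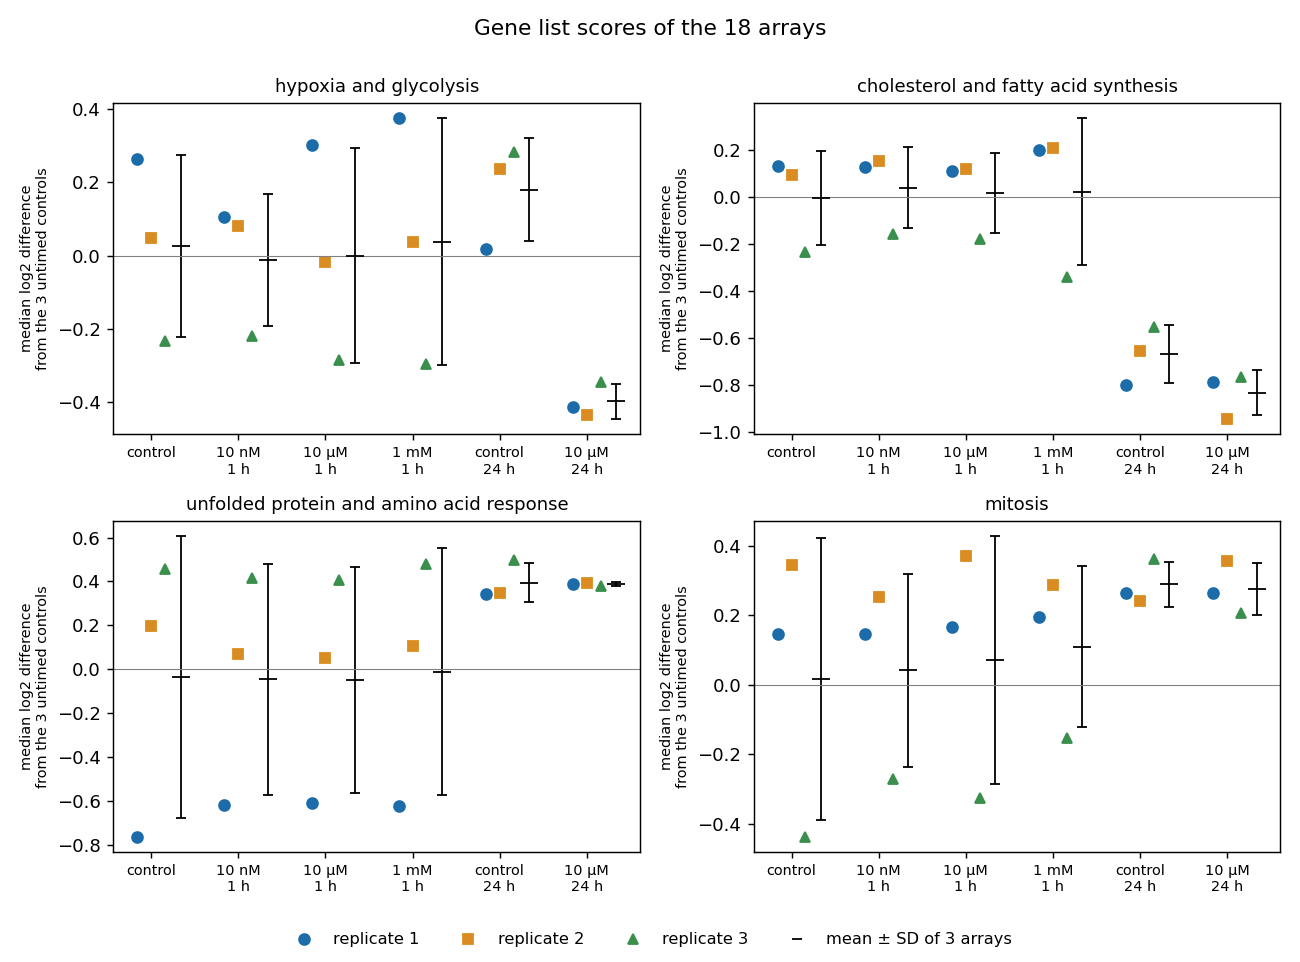
Score of 4 gene lists in each of the 18 arrays, as the median log2 difference of the list's genes from the mean of the 3 untimed controls; markers show the replicate number, and bars the mean ± SD of the 3 arrays of a group. In the hypoxia and glycolysis panel the 24 h nicotine arrays lie between -0.43 and -0.34 and the 24 h controls between 0.02 and 0.28, while in the unfolded protein and amino acid panel the 12 arrays of the 1 h doses and their controls average -0.65, 0.11 and 0.44 by replicate number.

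At 1 h the question was whether nicotine changes transcripts over a range of doses, and no probe set passed at any dose. With limma, 10 nM gave 0 called and 577 at an unadjusted p under 0.05, 10 µM gave 0 and 452, and 1 mM gave 0 and 680. These are 1.76%, 1.38% and 2.08% of the probe sets, below the share of 0.05 expected by chance. The fit leaves the differences between the replicate sets in its error, although the groups are balanced over them. Counts of 0 are therefore weak evidence of no change. The shares with the block of 3 sets were 3.98%, 3.18% and 5.45%. With the block of 3 sets, 10 nM and 10 µM again gave 0, with 1304 and 1043 unadjusted, and 1 mM gave 1, with 1786 unadjusted. A joint test of any dose gave 0 called and 523 unadjusted, and 0 and 1498 with the block. The probe set called with the block at 1 mM measures PABPC1L, a relative of the poly(A)-binding proteins: it rose by 0.79 ± 0.11, with an adjusted p of 0.0197, while its other probe sets differed by 0.32 and 0.10. In data simulated at this spread, the fit without a block found 6% of 1.5-fold, 26% of 2-fold and 92% of 4-fold changes at 1 mM. The fit with the block found 32%, 48% and 100%, with 5 false calls.

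The 1 h genes with the smallest p did not pass at any dose. At 10 nM the list was led by A1CF, an RNA editing cofactor, which differed by -1.43 ± 0.31 and stood at 4.24 ± 0.17 against 5.67 ± 0.09. At 10 µM the caspase CASP2 differed by -1.47 ± 0.31, at 4.91 ± 0.66 against 6.38 ± 0.38. At 1 mM the cytokine IL22 differed by -1.17 ± 0.25, at 4.58 ± 0.29 against 5.75 ± 0.09. Their adjusted p was 1.00 in each case. The levels with nicotine were near background, so the differences depend on the offset: over the alternatives A1CF ranged from -3.36 to -0.56, CASP2 from -2.36 to -0.73 and IL22 from -2.21 to -0.50. EGR1 differed by 0.01, 0.13 and 0.29 at the rising doses, each with an SE of 0.58, and CHRNA5 by 0.11, -0.10 and -0.03, each with an SE of 0.16. CD69, MYC and NFKBIA differed by between -0.20 and 0.30 at the 3 doses. IL2RA differed by 0.22, -0.68 and 0.14, each with an SE of 0.38, and was near background, at 4.27 with 10 µM.

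Among the 26 lists, 1 was called at 1 h against the untimed controls. Natural killer cell markers rose at 10 µM by a median of 0.19 over 5 measured genes, all with a higher mean, among them the lectin receptor KLRD1 at 0.87 ± 0.37 and perforin, PRF1, at 0.42 ± 0.26. The adjusted p was 0.0441, but an adjusted p of 0.198 with an estimated correlation, 0.538 with fry and 0.123 with the block of 3 sets. No member passed over all genes or adjusted over the list alone. KLRD1 was near background, at 5.52 with nicotine, and its difference ranged from 0.34 to 1.21 over the alternatives. Within the 3 replicate sets the list's median was -0.01, 0.36 and 0.31, and the call was lost without replicate 2 of the untimed controls and without replicate 2 or 3 of the 10 µM arrays, with adjusted p of 0.257, 0.298 and 0.147. At 10 nM the smallest adjusted p was 0.692, for nicotinic receptor subunits. At 1 mM these subunits had a median of 0.17 over 8 genes with an adjusted p of 0.113, and CHRNA2, CHRNA6 and CHRNB2 differed by 0.70 ± 0.35, 0.57 ± 0.30 and 0.72 ± 0.43 without passing. Over the alternatives these differences ranged from 0.21 to 1.14, 0.27 to 0.74 and 0.07 to 1.07. With the block of 3 sets, mitosis genes were called higher at 10 µM and 1 mM, with medians of 0.09 and 0.09 and adjusted p of 5.2e-04 and 3.2e-05, but an adjusted p of 0.560 and 0.837 with an estimated correlation. Without the block and without replicate 3 of the untimed controls, the medians turned to -0.13 and -0.14, and without replicate 2 of the 10 µM arrays that at 10 µM turned to -0.09. Without the block, leaving out 1 array called the list in 4 of 6 fits at 10 µM, 3 of them higher with medians up to 0.29, and in 3 of 6 at 1 mM, with medians up to 0.24.

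The doses were also compared with each other, which needs no control arrays. Immediate early genes were higher at 1 mM than at 10 µM by a median of 0.13 over 20 genes, of which 17 had a higher mean. The adjusted p was 0.0431, but an adjusted p of 0.541 with an estimated correlation, 0.855 with fry and 0.161 with the block of 3 sets. Erythroid and platelet markers were higher by 0.43 over 5 genes, of which 4 had a higher mean. Their adjusted p was also 0.0431, but an adjusted p of 0.424 with an estimated correlation, 0.855 with fry and 0.313 with the block. No member of either passed over all genes or adjusted over the list alone. Of the erythroid and platelet genes, ITGA2B and ALAS2 were near background, at 5.68 against 4.74 and 5.46 against 4.71. Both calls were lost without replicate 1 of either dose and without replicate 3 of the 1 mM arrays, and the first also without replicate 2 of the 10 µM arrays, with adjusted p from 0.0658 to 0.580. Without 1 array the median of the first lay between 0.04 and 0.27 and that of the second between 0.18 and 0.60, and over the alternatives the second ranged from 0.01 to 0.75. Between 1 mM and 10 nM no list was called, with a smallest adjusted p of 0.680, while 0 to 4 were called without 1 array. With the block of 3 sets mitosis genes were called, with a median of 0.07 and an adjusted p of 0.00559, but an adjusted p of 0.936 with an estimated correlation. Without the block and without 1 array they were called in 2 of 6 fits, and the median changed sign, from -0.09 to 0.23. Single probe sets gave 0 called for 1 mM against 10 nM, with 860 unadjusted, and 0 against 10 µM, with 726 unadjusted, by limma, and 0 for both with the block.

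Across probe sets, which are not independent replicates, the differences of the 1 h doses from their shared controls had Pearson correlations of 0.448, 0.446 and 0.452 and Spearman correlations of 0.404, 0.412 and 0.411. Groups simulated with no change on the same controls gave a mean Pearson correlation of 0.50 for each pair over 50 simulations. The simulation treats the arrays as independent, whereas those of equal number correlated, so the observed correlations are not a test of a response shared between doses.

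Whether the response to 10 µM nicotine differed between the times was tested as the difference of the 24 h and 1 h effects. The hypoxia and glycolysis list was lower at 24 h than at 1 h by this test, with a median of -0.61 and all 26 genes below 0, among them ADM at -2.60 ± 0.51 and PFKFB4 at -2.33 ± 0.73. EGLN3 was below 0 only marginally, since it differed from its controls by 0.18 at both times. The adjusted p was 1.1e-14, but an adjusted p of 0.0644 with an estimated correlation and 0.276 with fry. Cholesterol and fatty acid synthesis had a median of -0.27, with 19 of 23 genes below 0. Its adjusted p was 6.9e-04, but an adjusted p of 0.722 with an estimated correlation and 1.00 with fry. The differences of ADM and PFKFB4 ranged from -2.95 to -1.26 and from -3.65 to -1.31 over the alternatives. Over all genes 0 members of either list passed, and 1 of the hypoxia list was lower adjusted over the list alone. The call of the cholesterol list was lost without replicate 3 of the untimed controls, with an adjusted p of 0.230, and its median lay between -0.38 and -0.15 without 1 array. Single probe sets gave 0 called and 777 unadjusted by limma, and 3 called with the block: BNIP3, TPI1 and LDHA, which fell with differences of -1.94, -0.71 and -0.65 and are named here after their values were seen. The same BNIP3 probe set differed by -1.95 and -2.14 between the 1 h sets, for numbers 2 and 3 against 1. Its difference between times is no larger than that between sets.

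The untreated cells themselves differed between the 24 h controls and the untimed controls, a comparison of time in culture or of any other difference between those arrays. With limma, 1557 probe sets in 1104 genes passed, 667 higher and 890 lower at 24 h. The block of 3 sets gave 6843, but the 24 h controls belong to none of these sets and the block takes the spread between them out of the error, so this count is not relied on. Cholesterol and fatty acid synthesis fell by a median of 0.55, with an adjusted p of 2.1e-11, but an adjusted p of 0.150 with an estimated correlation. Of its 23 members 8 were lower over all genes and 14 adjusted over the list alone, among them the mevalonate decarboxylase MVD at -2.05 ± 0.30, the lanosterol synthase LSS at -1.59 ± 0.26 and the fatty acid synthase FASN at -1.25 ± 0.30. Genes of the mitochondrial respiratory chain fell by a median of 0.26, with an adjusted p of 3.3e-07, but an adjusted p of 0.357 with an estimated correlation. Of these 41 genes 5 were lower over all genes and 12 adjusted over the list alone, among them UQCRC1 at -1.10 ± 0.15 and COX6C at -0.71 ± 0.16. Oxidative stress genes fell by a median of 0.26, with an adjusted p of 0.00221, but an adjusted p of 0.357 with an estimated correlation. Thioredoxin TXN at -0.90 ± 0.17 and ferritin light chain FTL at -0.53 ± 0.14 were the 2 of 20 that passed over all genes, and 2 passed adjusted over the list alone. Lysosome and autophagy genes fell by a median of 0.20, with an adjusted p of 0.0257, but an adjusted p of 0.439 with an estimated correlation. Of 24 genes 2 were lower over all genes, ATP6V0D1 at -0.62 ± 0.15 and CTSA at -0.62 ± 0.17, and 4 adjusted over the list alone. Mitosis genes rose by a median of 0.28, with an adjusted p of 0.0184, but an adjusted p of 0.762 with an estimated correlation. The kinetochore motor CENPE at 0.97 ± 0.27 was the 1 member that passed over all genes, and 0 passed adjusted over the list alone.

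Without the block 5 lists were called and 0 with an estimated correlation. The block of 3 sets gave 10 and 3, which are not relied on for the same reason. One of those 3, the unfolded protein and amino acid response, was not called without the block, with a median of 0.39 and an adjusted p of 0.148. Its difference rests on replicate 1 of the untimed controls: the scores of these were -0.76, 0.20 and 0.46 against 0.34 to 0.50 at 24 h, and without replicate 1 the median was 0.01 with an adjusted p of 0.983. The call of lysosome and autophagy was lost without replicate 3 of the untimed controls and without replicate 1 or 2 of the 24 h controls, with adjusted p of 0.180, 0.0542 and 0.0702, and mitosis without replicate 3 of either control group, with 0.828 and 0.0670. The median of mitosis lay between 0.04 and 0.44 without 1 array. Single genes with the largest changes included ADM, which rose by 2.15 ± 0.36, the growth factor HBEGF, which rose by 1.81 ± 0.36, and EGR1, which rose by 2.08 ± 0.58. RSBN1L and LZTFL1 both rose by 2.28, and MACROD2 by 1.79. RHOT2, the secretory pathway cargo receptor TMED2, the NF-kB inhibitor NFKBIB, the nuclear long non-coding RNA MALAT1 and LINC02059 fell, with differences of -2.07, -2.08, -2.19, -2.03 and -2.26. The other RHOT2 probe sets differed by -1.65 and, for the brightest, -0.23, and those of EGR1 by 1.67 and 0.13. The 24 h controls are shared with the comparison of nicotine at 24 h, where ADM, EGR1 and RHOT2 differed by -2.17, -2.71 and 1.58. BNIP3 was mirrored as well, at 1.66 between the untreated groups and -1.92 with nicotine. For these genes, effects of time and of nicotine cannot be told apart from a deviation of the 24 h controls. PFKFB4 and PROSER2 were mirrored in part, at 0.80 and 0.89 between the untreated groups and -2.65 and -1.55 with nicotine. Where 1 group was near background the size depends on the offset: over the alternatives MVD ranged from -4.00 to -0.92, LINC02059 from -4.78 to -1.02, RHOT2 from -3.18 to -1.08 and ADM from 1.09 to 2.50. EGR1 passed in 8 of 18 alternatives and CENPE in 6 of 18. Of genes of acetylcholine signalling, the muscarinic receptor CHRM3 rose by 1.06 ± 0.18 and butyrylcholinesterase, BCHE, by 0.96 ± 0.23. The ACTB ratio was 1.49 to 2.32 in the untimed controls against 2.69 to 3.27 in the 24 h controls. The count was 834 and 809 without replicate 1 or 2 of the untimed controls and 635, 732 and 897 without replicate 1, 2 or 3 of the 24 h controls.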

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

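Leaving out single arrays was fixed beforehand, but its use to weigh a cause was chosen after the result was seen. The tests with matched random lists, differences between cultures and other splits were also chosen only then. The test of the difference between times was planned. The median difference between the 24 h and 1 h effects of 10 µM nicotine was -0.61 for the hypoxia and glycolysis list and -0.27 for the cholesterol and fatty acid synthesis list, and both are given here because the effect of 1 dose differed between 2 times by camera. The hypoxia list had an adjusted p of 1.1e-14 and all 26 genes below 0, EGLN3 only marginally. Its adjusted p was 0.0644 with an estimated correlation, and from 1.1e-32 to 0.276 over its 12 alternatives. The cholesterol list had an adjusted p of 6.9e-04 and 19 of 23 genes below 0, but an adjusted p of 0.722 with an estimated correlation, and from 4.1e-07 to 1.00 over its 12 alternatives. Of 100 pairs of splits of the arrays within each time, 69 gave as many called lists as the real 2, and the highest other gave 11. Many of these splits mix the replicate sets of the 1 h arrays, which the real groups balance: of the 60 that part fewer pairs of equal number than the real groups, 56 gave as many lists. Of the 40 that part all 3 pairs, the real one included, 13 gave as many lists and the highest other gave 3, so chance cannot be excluded for the number of lists. For single probe sets the real count was 0, which 100 of 100 pairs of splits reached, with a highest other of 1.

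The lower hypoxia and glycolysis genes at 24 h with nicotine are the pattern behind the first of these results. The tables argue against a single array as the cause, since the median without any one array was at most -0.482. Of 10000 random lists matched on mean level, 0 had a median as low and the lowest was -0.134. The list thus stood apart from other genes of like brightness in the normalized values. A shift of all such genes cannot be tested this way, since quantile normalization takes most of it out beforehand. A difference between the cultures other than nicotine, such as cell density or oxygen, cannot be told apart from nicotine: the list score ranged over 0.495 among the 3 untimed controls, against a difference of -0.577 at 24 h, and the labels do not say whether the 24 h arrays of a group come from separate cultures. The 10 splits of the 6 arrays at 24 h are too few for a share under 0.05; the real absolute median was 0.548 and the highest other 0.345. A lower hypoxia response after nicotine remains a hypothesis that may be tested in cultures matched for density.

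The 24 h nicotine count of 1 probe set and 2 lists compares with a highest other split of 0 probe sets and 5 lists; 1 of 10 splits gave as many probe sets and 4 of 10 as many lists, and 10 splits are too few for a share under 0.05. The same limit holds for the other comparisons of 3 arrays with 3. At 10 nM the real count was 0 and the highest other 1, at 10 µM 0 and 0 for probe sets and 1 and 10 for lists, which 7 splits reached, and at 1 mM 0 and 0. Many of the 1 h splits mix the replicate sets, which the real groups balance, so their counts are no fair measure of chance. Between doses the real counts were 0, with a highest other of 0 for 1 mM against 10 nM and 1 for 1 mM against 10 µM. A real count of 0 is reached by all 10 splits. Between the untreated groups the real count was 1557 probe sets against a highest other of 0, and 5 lists against 9, which 5 splits reached.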

How the results depend on the processing

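The block of 3 sets, that block with an estimated correlation, and for lists median centring and the arrays compared alone were chosen after the data were seen. Over all alternatives, counts and correlations gave 345 values, of which 244 stayed within 1.5 times the reported count or 1 SD and 101 moved. Lists gave 387 values: 276 kept direction and side of the threshold, 58 lost the call, 47 gained one, 5 moved and 1 reversed. The named genes gave 3500: 3161 kept, 154 lost, 127 gained, 58 moved and 0 reversed, where a gene called in neither fit that changed sign counts as moved. The hypoxia and glycolysis list at 24 h was called in all 12 alternatives, with medians from -0.56 to -0.53, and in all 6 fits without an array. The 1 reversal is the mitosis list at 10 µM and 1 h without replicate 3 of the untimed controls, at -0.13; without other arrays it lay up to 0.29. At 1 mM that list, called in neither fit, lay at -0.14 without the same array. Unless fewer arrays or probe sets explain a change, the cause was not tested. Under no scaling was the median difference over all probe sets beyond 0.1. The largest was 0.0503, between the untreated groups with the values as deposited. Dim signals near the background limit the folds of genes such as RHOT2 and ADM.

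Counts of probe sets that moved were as follows. Without the filter, 1 at 10 µM and 1 for any dose at 1 h (LINC02582, named after its value was seen). At 24 h with nicotine, 0 with an offset of 64, as deposited, without the filter and with 1 probe set per gene, 19 with the arrays compared alone, 3 with array weights (RHOT2, IGFBP2 and ADM), 32 with the planned block, 43 with the block of 3 sets, and 0 to 3 without 1 array: 0 without replicate 3 of the controls or any nicotine array, 3 without replicate 1 of the controls and 1 without replicate 2, which was MED23 in place of RHOT2. At 1 mM the block of 3 sets gave 1. For the difference between times the planned block gave 1 (BNIP3) and the block of 3 sets 3. Between the untreated groups the arrays alone gave 883, array weights 3337, 1 probe set per gene 643, the planned block 5201 and the block of 3 sets 6843, with 635 to 1191 without 1 array.

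Counts of lists that moved were, at 10 nM, 2 as deposited, 1 with median centring and 0 to 5 without 1 array. At 10 µM and 1 h they were 0 with the estimated correlation, fry, the median over probe sets, no filter, an offset of 1, as deposited, median centring and the block of 3 sets with an estimated correlation, 3 with the planned block, and 0 to 5 without 1 array. At 1 mM they were 2 as deposited and with median centring, 1 with either block, and 0 to 2 without 1 array. At 24 h with nicotine they were 1 with the estimated correlation and fry, 4 as deposited, with median centring and with the arrays alone, and 2 to 3 without 1 array. For 1 mM against 10 nM they were 1 with the block of 3 sets and 0 to 4 without 1 array. For 1 mM against 10 µM they were 0 with the estimated correlation, fry, no filter, an offset of 1 and each block, and 1 to 3 without 1 array. For the difference between times they were 0 with the estimated correlation and fry, 1 with the median over probe sets and with the block of 3 sets and an estimated correlation, and 2 to 4 without 1 array. Between the untreated groups they were 0 with the estimated correlation, 3 with the median over probe sets and with the block of 3 sets and an estimated correlation, 9 without the filter and with the arrays alone, 8 with the planned block, 10 with the block of 3 sets, and 4 to 8 without 1 array. Correlations between doses were 0.465 and 0.464 without the filter for 10 nM with 10 µM and with 1 mM. Without 1 control array they were 0.603 to 0.634, 0.593 to 0.628 and 0.595 to 0.638, since fewer shared controls raise the shared part.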

Other observations

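The tests in this part were chosen only after the grouping of the arrays was seen. The 1 h arrays and their untimed controls grouped by replicate number. On residuals from the group means, each of the 12 arrays correlated best, among arrays of other groups, with one of its own number. The residuals leave out differences between doses, so this check cannot weigh number against dose. The arrays of number 3 expressed genes of the unfolded protein and amino acid response far above those of number 1, the unnumbered nicotine arrays counted as number 1. The list's median rose by 1.27 log2 units over 26 genes, with an adjusted p of 1.0e-09 and an adjusted p of 0.0131 with an estimated correlation. TRIB3, a pseudokinase induced by this response, rose by 3.76 ± 0.07 (SE, 4 arrays against 4), the transcription factors CEBPB and ATF4 by 1.64 ± 0.07 and 0.91 ± 0.05, and the asparagine synthetase ASNS by 1.53 ± 0.09. Much of the list's difference lay between number 1 and the other sets. Number 2 was above 1 by a list median of 0.88, with an adjusted p of 0.00559 with an estimated correlation. Number 3 was above 2 by 0.23, with an adjusted p of 0.00344 by camera but 0.0864 with an estimated correlation. From number 2 to 3, TRIB3 and CEBPB rose by 2.25 and 0.71, while ATF4 and ASNS differed by -0.03 and -0.22. Genes named in this part were chosen after their values were seen. The 4 arrays of a number may share 1 culture or occasion. The SEs, adjusted p and counts given for differences between numbers therefore measure the spread within sets only.

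The arrays of number 3 also had lower levels of heat shock genes than those of number 1. The median was -0.93 with an adjusted p of 0.0137 with an estimated correlation, and the chaperone HSP90AB1 differed by -1.56 ± 0.07. Ribosome biogenesis and DNA replication were lower by medians of -0.61 and -0.33, with adjusted p of 0.0412 and 0.0137 with an estimated correlation, and the respiratory chain by -0.24, with 0.0452. For the respiratory chain, number 3 against 2 gave only -0.05, with an adjusted p of 0.225 with an estimated correlation. Number 2 against 1 gave -0.13, with 0.0662. The hypoxia and glycolysis list was lower by -0.45 with an adjusted p of 4.97e-04, but an adjusted p of 0.170 with an estimated correlation. Mitosis was lower by -0.41 with an adjusted p of 5.6e-07, but an adjusted p of 0.162 with an estimated correlation, and CENPF differed by -1.11 ± 0.07. Genes of the T lineage and T cell receptor were not called, with a median of 0.15 and an adjusted p of 0.159, and among single genes CD1A, CD1C and DNTT differed by -1.90 ± 0.09, -1.56 ± 0.07 and -1.33 ± 0.06. The class I molecule HLA-B and the glucose-sensitive TXNIP were higher by 1.89 ± 0.07 and 2.42 ± 0.07. Between sets, 11101 probe sets differed for number 3 against 1, 4674 for number 2 against 1 and 8145 for number 3 against 2.

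The grouping by number may reflect cultures or handling on different occasions, which no label gives. Of 10000 matched random lists, 0 had a median as high as the amino acid response list in the third set over the first, with 0.382 the highest. This cannot test a shift of all genes of like brightness, since quantile normalization takes most of it out beforehand. The tables argue against RNA quality read as the ACTB ratio as the whole cause: number 3 had the middle ratio, but its list score lay beyond those of both other sets by 0.334. No biological explanation was tested, since the design names none.

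The joint test of any dose was also run on 100 groupings of the 12 arrays at 1 h, the real one included. The real count was 0, which 100 of 100 groupings reach, and the highest other was 6039. That grouping kept 9 of the 18 pairs of equal number together, the most of any, whereas the real groups keep 0, and 16 groupings called any probe set. The high counts of some groupings point to a structure of the arrays, which the grouping by number had already shown; they are not a separate test of it, and groupings that kept 6 pairs together called between 0 and 3078 probe sets. With the block of 3 sets the joint test called 0.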
